A study of Homo sapiens with 2 samples.

How the data were processed

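Total RNA of primary human umbilical vein endothelial cells (HUVECs) was sequenced in 2 libraries. Both came from cells infected at passage 4 with a lentivirus that carries the human progesterone receptor (PR). One library is PR only, and the other is PR plus 100 nM progesterone for 4 h, given 3 days after confluence. Each group holds 1 library. Whether the PR-only cells received a vehicle is not given in the sources used here. Reads were 50 nt long, per the labels' protocols.

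TopHat2 2.0.4, Cufflinks 2.0.1 and Cuffdiff are named with build hg19 in the submitters' processing notes, with no role or order. Each deposited file is a Cufflinks transcript assembly of 1 library, per the file headers of its source column. The deposited FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) has a lower and an upper limit for each assembled transcript. The deposited score, a whole number for each transcript, was not used here. Loci and transcripts carry only the assembler's running numbers. The deposited files do not pair these numbers with gene names, and an annotation of build hg19 was not used here. No gene is therefore named: the level of the PR transgene, the genes and the gene lists chosen before the data were examined are not analysed here, and results are given for numbered loci with hg19 positions.

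The depth was read from the files. FPKM divided by the deposited coverage was 0.495 in PR only and 0.597 in PR + progesterone, which with 50-nt reads implies 40377788 and 33480977 fragments. For loci with 1 transcript longer than 600 nt and a positive lower limit, the limits were read as 2 Poisson standard deviations around the FPKM. The fragment count that this implies was set against the count from coverage and length. A length offset of 203 nt in each library was first fitted as a median over these same loci. The counts then matched to a relative tolerance of 0.01 for 91.4% of 17113 loci in PR only and 91.3% of 18178 loci in PR + progesterone. For the loci within this tolerance the limits match counting error. The limits of shorter loci and of loci with more than 1 transcript were not checked in this way. With 1 library per group, no limit covers the spread between cultures.

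Loci on chromosomes X and Y were left out, so that no sex-linked level of a donor is used. The running numbers differ between the libraries, so loci were paired by position on hg19, which both libraries share. A pair lay on the same chromosome with the same deposited strand symbol, and shared at least 80% of the exonic bases of each library's locus. The strand was not checked beyond this symbol. This pairing rule was set after the structure of the files was seen. The level of a locus was the sum of FPKM over its transcripts, and its limits were the summed limits. The ratio was log2((FPKM with progesterone + 1)/(FPKM without + 1)) for loci of at least 1 FPKM in the higher library. On this scale the difference of low loci is understated. With 1 library per group there was no test, and no p-value is given. Loci were counted at 2-fold in each direction. The extremes are the 12 highest and 12 lowest ratios among loci of at least 5 FPKM in the higher library, a longest transcript of at least 300 nt and limits that do not overlap. Of these, 2 per direction are given by number.

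The alternatives fixed before the data were examined were pseudocounts, filters, scalings, the most abundant transcript, the transcript length, the limits and a threshold of 1.5-fold. Other pairing rules, spliced loci alone, loci of at least 1000 nt, the same total on the FPKM scale and the mean FPKM over the bases assembled in both libraries were added after seeing the data. An earlier exploration of the same files, which is not reported, also informed the pairing rule.

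The steps were tested on simulated data. For progesterone against no progesterone, a second library was drawn with Poisson counts over 9633 loci, with 200 loci given known folds. Of 50 loci at a fold of 4, 100% were counted as higher, and of 50 loci at a fold of 0.25, 80% were counted as lower. At a true fold of 2, 16% of 50 loci passed, and at 0.5, 24% of 50 loci passed. Of 9433 loci left as they were, 0.19% passed, 0 as higher and 18 as lower. The draw held counting error on the same loci, without a spread between cultures or a difference in assembly. This percentage is therefore no background rate for the counts in the real libraries. When 41306 loci were paired with trimmed copies of themselves, 100% found their copy and 0 were paired wrongly. A trimmed copy keeps the position of its locus, so this checks the pairing step only and not the pairing of 2 separate assemblies. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.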

Results

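The transcriptome of HUVECs, primary endothelial cells from the umbilical vein, was measured by RNA sequencing after infection with a lentivirus that carries the human progesterone receptor (PR), a steroid-activated transcription factor. One library came from infected cells without progesterone and the other from infected cells given 100 nM progesterone for 4 h. The comparison asks which transcripts differ when the ligand is added to cells that carry the receptor. There was 1 library per group, so no difference below has a replicate check. The PR-only library held 47918 assembled transcripts in 42906 loci from an implied 40377788 fragments. The PR + progesterone library held 52267 transcripts in 47270 loci from an implied 33480977 fragments. Loci carry running numbers in place of gene names, so the comparison is given by locus and hg19 position.

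Most loci paired between the libraries lay within 2-fold. Of 9644 paired loci at 1 FPKM or more in the higher library, 264 (2.74%) were at least 2-fold higher with progesterone and 181 (1.88%) were at least 2-fold lower. The median log2 ratio was 0.05 and its SD over loci was 0.48. These paired loci are a part of the assemblies: 9657 pairs held 23.4% of the PR-only loci and 21.2% of the PR + progesterone loci outside chromosomes X and Y. The counts moved with the pairing rule, to 1221 higher and 740 lower of 19374 loci at 50% shared bases, and to 76 and 47 of 4119 loci at 95%. The percentage of paired loci past 2-fold also fell as the rule became stricter, so it depends on this choice. Higher loci made up 59.3% of the loci past 2-fold (95% exact binomial interval 54.6% to 63.9%, counting loci as independent). This interval and those below describe the loci of these libraries and do not cover the spread between cultures. The share was 59.9% (55.2% to 64.5%) with both libraries at the same upper quartile. With median centring, which itself fixes the middle of the ratios, it was 51.1% (46.2% to 55.9%), with 218 loci higher and 209 lower. The share was 49.0% (44.2% to 53.8%), with 212 loci higher and 221 lower, when the libraries were scaled to the same total FPKM. This total covers all loci outside chromosomes X and Y, paired or not, whereas the upper quartile was taken over the paired loci. TPM applies that same scaling with a pseudocount of 1 TPM, worth 6.86 FPKM here, and with this larger pseudocount the counts were 95 higher and 125 lower (43.2%, 36.5% to 50.0%). The deposited limits did not overlap for 3830 loci (39.7%), of which 2091 were higher and 1739 lower with progesterone. Among the loci past 2-fold, the limits did not overlap for 218 of the higher and 162 of the lower loci. The limits do not cover the spread between cultures, and lay a median of 12.1% of the FPKM to either side in PR only and 13.1% in PR + progesterone.

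**Figure D1:**
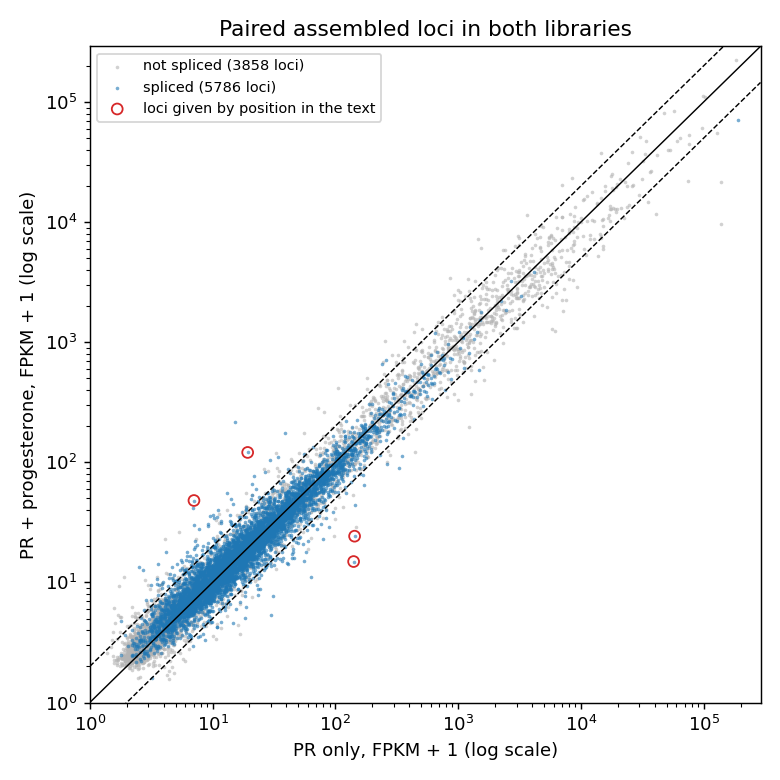
FPKM + 1 of the 9644 paired loci, PR only on the x axis and PR + progesterone on the y axis, both on log scales, with spliced and unspliced loci in separate colours. The solid line marks equal values and the dashed lines a 2-fold ratio, and 264 loci lie at or above the upper and 181 at or below the lower dashed line.

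Spliced and unspliced loci were described separately. Of 5786 loci spliced in both libraries, 117 (2.02%) were at least 2-fold higher with progesterone and 84 (1.45%) at least 2-fold lower, with a median log2 ratio of 0.03 and an SD of 0.44. Among the other 3858 loci, 147 (3.81%) were higher and 97 (2.51%) lower, with a median of 0.09 and an SD of 0.52. By mean level, 21 loci were higher and 9 lower of 1271 below 3 FPKM, 81 and 29 of 2539 at 3 to under 10, 70 and 40 of 2727 at 10 to under 30, and 37 and 45 of 1689 at 30 to under 100 FPKM. Among 1418 loci with a mean of 100 FPKM or more, 55 were higher and 58 lower. The deposited limits lay a median of 32.4% (PR only) and 33.1% (PR + progesterone) of the FPKM to either side below a mean of 3 FPKM, 5.39% and 6.12% at 30 to under 100 FPKM, and 20.3% and 22.5% at 100 FPKM or more.

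**Figure D2:**
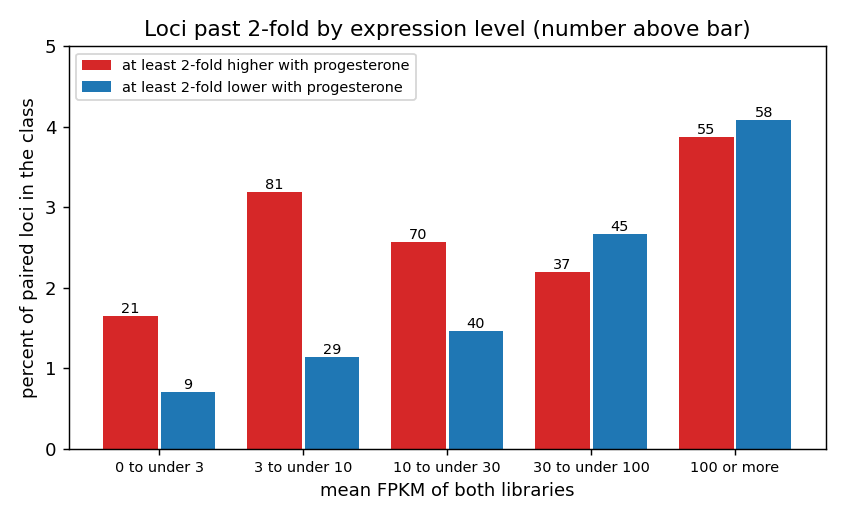
Percent of paired loci at least 2-fold higher or lower with progesterone, in classes of the mean FPKM of both libraries, with the number of loci above each bar. Higher loci outnumber lower ones below 3 FPKM (21 and 9), at 3 to under 10 FPKM (81 and 29) and at 10 to under 30 FPKM (70 and 40). The numbers are 37 and 45 at 30 to under 100 FPKM and 55 and 58 at 100 FPKM or more.

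The 12 highest ratios lay between 2.09 and 2.77 on the log2 scale, on 9 chromosomes, and 9 of these loci were spliced. Locus CUFF.37973 of the PR-only library (CUFF.41648 with progesterone) lay on the plus strand of chromosome 7 from 94028367 to 94039135 on hg19 and had up to 16 exons. Its FPKM was 6.06 (limits 5.15 to 6.96) in PR only and 47.1 (29.7 to 64.5) with progesterone. Over the bases assembled in both libraries the log2 ratio was 0.77 in place of 2.77. With progesterone the locus held 2 transcripts, the longest 739 nt of 917 assembled nt. Most of the 47.1 FPKM lay on the shorter transcript, which the ratio of 0.77 also includes. Locus CUFF.6578 (CUFF.7194 with progesterone), on the minus strand of chromosome 11 from 36295019 to 36310967, had an FPKM of 18.3 (17.2 to 19.4) in PR only and 119.9 (98.7 to 141.1) with progesterone. Its log2 ratio was 2.64, and 0.59 over the shared bases.

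The 12 lowest ratios lay between -3.24 and -1.70, on 9 chromosomes, and 9 of these loci were spliced. Locus CUFF.23483 (CUFF.25780 with progesterone), on the minus strand of chromosome 2 from 99785826 to 99797507, had an FPKM of 140.0 (104.0 to 176.0) in PR only and 13.9 (12.2 to 15.6) with progesterone. Its log2 ratio was -3.24, and -1.40 over the shared bases. Locus CUFF.2628 (CUFF.2888 with progesterone), on the minus strand of chromosome 1 from 150594356 to 150599007, had an FPKM of 142.6 (129.1 to 156.1) in PR only and 23.3 (21.6 to 24.9) with progesterone. Its log2 ratio was -2.56, and -0.84 over the shared bases. In each of these 4 loci the number of assembled transcripts differed between the libraries, 1 in one library and 2 in the other, and the summed FPKM included the additional transcript. In the library with 2, the mean over shared bases lay below the summed FPKM, although the longest transcript covered most of these bases. Most of the summed FPKM there therefore lay on the shorter transcript, whose length and own FPKM are not given here.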

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

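The main counts were 264 loci at least 2-fold higher and 181 lower. Spliced loci alone, other shared-base rules, the same total on the FPKM scale, the mean over shared bases and loci of at least 1000 nt were chosen after seeing the data. Under the pseudocounts, the filters on FPKM, median centring, the upper quartile, the same total on the FPKM scale, the most abundant transcript, the limits and the mean over shared bases, both counts stayed within 1.5 times. TPM, the same total with a pseudocount worth 6.86 FPKM, gave 95 higher loci and 125 lower. Leaving out loci under 300 nt gave 162 and 106, spliced loci alone 117 and 84, and loci of at least 1000 nt 102 and 71, each from fewer loci. With 50% shared the counts were 1221 and 740 of 19374 loci, and with 95% shared 76 and 47 of 4119. At 1.5-fold they were 1011 and 661. The fall from 212 and 221 at the same total came from that pseudocount. Of 28 values for the 4 numbered loci, 22 moved by less than the deposited limits and 6 by more, and none changed sign in these settings: the mean over shared bases moved all 4. No value of the most abundant transcript could be given for these loci, which shared no intron chain between the libraries. The gene list, named gene and PR alternatives fixed beforehand were not run, since no gene is named here. No paired analysis was possible because each group holds 1 library. The effect of depth on the counts was not tested.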

Other observations

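Of 5786 paired spliced loci, 3980 (68.8%) had at least 1 intron chain that was the same to the base in both libraries, and 3916 had 1 transcript in both. Among 2872 pairs of adjacent spliced loci, 2 pairs were both at least 2-fold higher and 1 pair was both at least 2-fold lower with progesterone. Random placements matched on level gave medians of 1 and 0 pairs, with ranges of 0 to 4 and 0 to 3 in the central 95% of 10000 placements, as a description of these libraries.

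Spliced loci with no exonic base assembled in the other library lie outside the paired comparison, and their level in that library was not measured. Those with a longest transcript of at least 300 nt and a positive lower limit were counted. With progesterone there were 328 such loci, of which 59 were at 5 FPKM or more, with a median of 2.89 FPKM and a highest value of 91.0 FPKM. The PR-only library held 392, of which 40 were at 5 FPKM or more, with a median of 2.25 FPKM and a highest value of 1321 FPKM. A locus that was not assembled cannot be read as one that was not expressed.

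The tests on shared bases, on loci of at least 1000 nt and on the same total FPKM were added after the data were seen, and the bounds of all the tests below were set after a surplus of higher values had been seen. More loci were at least 2-fold higher than lower with progesterone, a share of 59.3%. This surplus lay below a mean of 30 FPKM. The numbers were 37 higher and 45 lower at 30 to under 100 FPKM, and 55 and 58 at 100 FPKM or more. With the mean FPKM over shared bases the share was 61.0% (55.8% to 66.1%). This mean still uses the FPKM given to each library's own transcripts. It therefore cannot decide on different assembled extents or transcript sets, which stay open. Short fragments with unstable FPKM stay open, with 59.0% (51.2% to 66.4%) among loci of at least 1000 nt. Scaling also stays open, with 49.0% (44.2% to 53.8%) at the same total FPKM but 59.9% at the same upper quartile. The total includes unpaired loci and the upper quartile does not, so these scalings rest on unlike sets of loci. Median centring, which itself fixes the middle of the ratios, gave 51.1% (46.2% to 55.9%). The effect of depth on the surplus was not tested, with an implied 40377788 fragments in PR only and 33480977 in PR + progesterone. A response to progesterone was not tested, since each group had 1 library.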
